A study of Homo sapiens with 17 samples.

How the data were processed

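Single-cell RNA was measured in 17 skin libraries of 3 groups, per the labels: healthy skin (6 libraries), nonlesional vitiligo skin (5) and lesional vitiligo skin (6). Per the labels' protocols, the skin was digested to single cells with a whole skin dissociation kit and the libraries were made with the 10x Chromium 5′ dual index chemistry, which counts molecules by unique molecular identifiers (UMIs). The labels name 12 separate donors, of whom 5 gave both lesional and nonlesional skin and 1 gave lesional skin only. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalisation, per the file headers and as checked on the values. Per the submitters' processing notes, reads were aligned to GRCh38 with Cell Ranger 7.2.0, whereas the file headers name version 7.1.0 in 8 libraries (3 healthy, 2 nonlesional and 3 lesional) and version 7.2.0 in 9 (3 of each group). Each deposited barcode already had at least 500 UMIs, so cells had been called before the files were deposited. No 2 libraries were copies of each other: of 136 library pairs, 0 were identical, and the highest correlation of log CPM (counts scaled to a common library total) was 0.991.

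Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs, which left 22466 of 24746. Scrublet in scanpy 1.11.5, run per library with its own threshold, called 45 doublets (0.200%), which were removed, and 22421 cells stayed. Because 0.200% is low for droplet data, removal at an expected rate of 0.8% per 1000 barcodes (362 cells) was run as an alternative. The libraries held from 1295502 to 16425673 UMIs (median 5562161) and from 196 to 3307 kept cells, and the median UMIs per kept cell ranged from 2113.5 to 5927.5. From 2.0% to 16.6% of the barcodes of a library were above the mitochondrial limit. The cells of all libraries were clustered together without integration, on 2000 variable genes scaled to 10000 counts per cell, 30 principal components, a graph of 15 neighbours with at least 3 shared, and Leiden clustering at resolution 1.0 with 5 iterations (leidenalg 0.10.2, igraph 0.11.9, seed 1). Sex-linked genes and the variable genes of T cell receptors and immunoglobulins were left out of the clustering.

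The 46 clusters were named from fixed markers of 13 classes. A cluster took the name of its best class when it held at least 50 cells and when at least 40% and at least 3 of the markers of that class were found in at least 25% of its cells at 2-fold or more over the other cells. Its 10 leading genes had to hold at least as many markers of that class as of all others, with keratins there admitted only for keratinocytes and sweat gland cells, and clusters of low UMI count needed a marker among them. These naming thresholds were set after the clusters were seen. The rules named 28 clusters and left 18 unnamed, with 2606 cells (11.6%). The mean unnamed share was 9.66% in healthy, 11.7% in nonlesional and 11.5% in lesional libraries. The named classes are clusters with the markers of a cell type, not sorted cells, and are written as keratinocyte-like, T/NK-like and so on at first mention. No cluster was named as mast, B/plasma or erythrocyte cells.

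Class shares are percents of all kept cells of a library and were compared by two-sided exact permutation tests of the difference in means, with Benjamini-Hochberg adjustment over 11 classes, the unnamed cells included. Intervals of pooled shares are exact Clopper-Pearson 95% intervals, and a count of 0 was given an upper limit of 3 counts. Intervals and limits cover counting error only and not the spread between donors. For gene tests, counts were summed per library and class over at least 20 cells, in classes with at least 3 such libraries in each group compared. This admitted keratinocytes, T/NK cells, fibroblasts and vascular endothelial cells in every comparison and myeloid cells between lesional and nonlesional skin, and it admitted no melanocyte comparison. Fold changes come from edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, robust quasi-likelihood fit of all 3 groups), with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. Levels are means of library CPM by edgeR with their SD, and fold changes carry their SE. XIST, TSIX and genes of the Y chromosome were left out of every test.

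The 36 gene lists, the cell markers, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 4 tested genes were compared with the other genes of the class by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over all list and class pairs of a comparison. The rule named, per comparison and class, up to 3 genes per direction past the threshold, up to 3 members with the smallest p of each called list, and fixed readout genes. Some genes that the rule named are not reported here. Genes picked in another way are introduced as chosen after their values were seen. Genes of the HLA family share sequence and vary between donors, so reads of some alleles can be counted against another gene or lost, and their values are uncertain in that respect. The same holds for gene pairs with near-identical copies, such as HSPA1A with HSPA1B and LGALS7 with LGALS7B.

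Alternatives planned before were DESeq2 1.42.0, RLE size factors, no filter on low counts, sums of at least 50 cells, fits of only the 2 groups compared, a 10% mitochondrial limit, doublets kept, shares of cells other than keratinocytes, each library left out, the donor as a block, camera with an estimated correlation, and fry. Alternatives added after the data were seen were the Cell Ranger version as a term, each version alone, doublets removed at the expected rate, sums of at least 10 cells, sums of at least 5 cells for melanocytes, voomLmFit in limma, keratinocyte clusters with a marker among their 10 leading genes, and melanocytes per 100 keratinocyte-like and melanocyte-like cells in libraries with at least 20 of these cells. The block pairs libraries of 1 donor, as the labels give them. Deviations of gene levels from the group means correlated within donors in endothelial sums at a mean r of 0.422 (5 pairs, lowest 0.215), in fibroblast sums at 0.436 (4 pairs, lowest 0.143) and in keratinocyte sums at 0.249 (4 pairs, lowest -0.0964), across genes, which are not independent. Libraries of different donors gave means of -0.0838, -0.0878 and -0.0482. The gene test was tested on simulated data with 200 changed genes per fit at the spread of these sums. The counts were drawn independently for each library, without donor pairs or other structure of the samples. Fits with fewer changed genes, where the adjustment is stricter, were not simulated, so the rates below may be too high for these data. In lesional against healthy skin it called 72% of 2-fold and 95% of 4-fold changes in endothelial sums, 39% and 88% in fibroblasts, 41% and 91% in T/NK cells, and 29% and 74% in keratinocytes. For myeloid cells, lesional against nonlesional, it called 20% and 83%. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.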

Results

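Expression was measured by 5′ single-cell RNA sequencing in skin of healthy donors (6 libraries) and in nonlesional (5) and lesional (6) skin of donors with vitiligo, a disease in which the skin loses its melanocytes and its colour. After filtering there were 5446 healthy, 6028 nonlesional and 10947 lesional cells, with 196 to 3307 cells and 1295502 to 16425673 UMIs per library. The group medians of the UMIs per cell lay close together, at 2752.25 in healthy, 2475 in nonlesional and 2516.75 in lesional skin. Vascular endothelial-like cells were the most abundant class in each group, with keratinocyte-like, fibroblast-like and mural-like cells among the next. Sweat gland-like cells stood at 13.9% ± 17.1 in healthy, 12.6% ± 14.2 in nonlesional and 5.17% ± 4.70 in lesional libraries. By the exact permutation test their lesional share was not called against healthy (adjusted p = 0.61) or nonlesional skin (adjusted p = 0.976). The series asks how immune programmes differ between affected skin, unaffected skin of the same donors and healthy skin. The comparisons of either vitiligo group with healthy skin share the 6 healthy libraries.

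**Figure D1:**
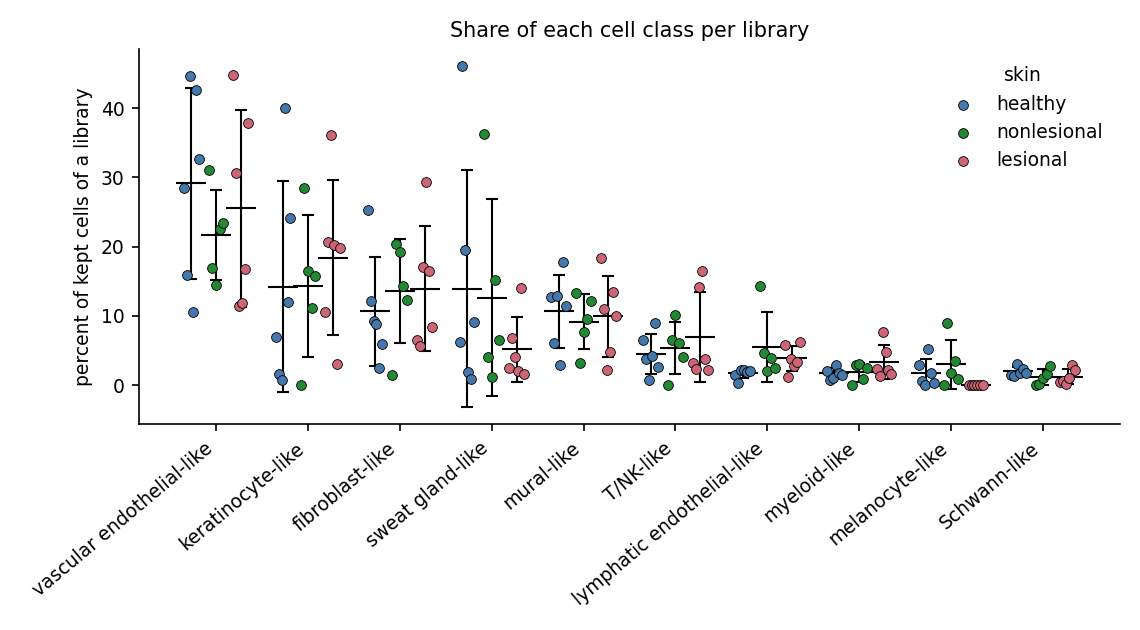
Share of kept cells (percent, vertical axis) of 10 named cell classes in healthy (n = 6), nonlesional (n = 5) and lesional (n = 6) libraries; points are libraries, dashes means and bars SD. Vascular endothelial-like cells had the highest means (29.1%, 21.7% and 25.5%), and melanocyte-like cells made up 1.80%, 3.03% and 0.0172%.

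Lesional against healthy skin asks what differs in affected skin from skin without the disease. Melanocyte-like cells, the pigment cells, made up 0.0172% ± 0.0273 of the cells of lesional libraries (SD, n = 6) and 1.80% ± 1.97 of those of healthy libraries (n = 6). Only 3 of 10947 lesional cells were of this class (0.0274%, 95% Clopper-Pearson interval 0.00565 to 0.0801%), in 2 of 6 libraries. In healthy skin it was 88 of 5446 cells (1.62%, interval 1.3 to 1.99%), in 5 of 6 libraries. In lesional replicates 1, 2, 5 and 6 no melanocyte-like cell was found. This allows shares of up to 0.231%, 0.25%, 0.125% and 0.718%, and healthy replicate 3 also had none (up to 0.542%). The exact permutation p was 0.0152 (two-sided) and 0.131 after adjustment over 11 classes, and it reached an adjusted 0.0238 only without healthy replicate 3, the healthy library with no such cell. Without any 1 of the other 11 libraries the adjusted p was from 0.167 to 0.405. The difference of -1.78 percentage points was -1.10 without healthy replicate 4. A measure relative to the epidermal cells was chosen after the data were seen. Lesional libraries held 0.0694 ± 0.121 melanocyte-like cells per 100 keratinocyte-like and melanocyte-like cells (n = 6) and healthy libraries 16.5 ± 11.7 (n = 5). The exact p was 0.00216, the smallest this design can give. Healthy replicate 3 held too few of these cells for the measure and was left out. The share test passed only without that same library, so this p is not independent of that result.

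**Figure D2:**
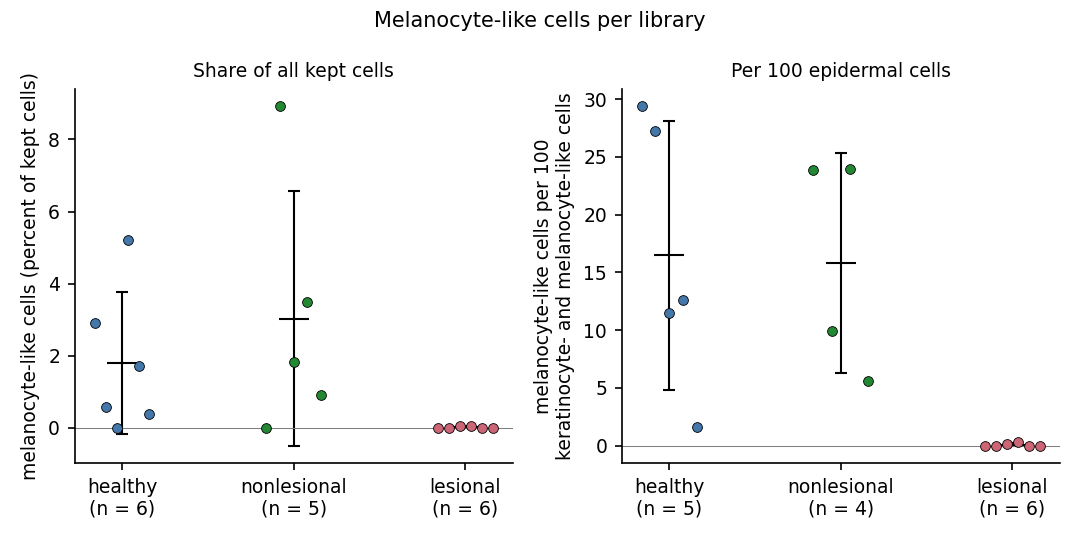
Melanocyte-like cells as a percent of kept cells (first panel; n = 6, 5 and 6 for healthy, nonlesional and lesional libraries) and per 100 keratinocyte-like and melanocyte-like cells (second panel; n = 5, 4 and 6), with points for libraries, dashes for means and bars for SD. The lesional means were 0.0172% and 0.0694 per 100, and the healthy means were 1.80% and 16.5 per 100. The healthy and the nonlesional library with no melanocyte-like cell held too few of these cells for the second panel.

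Within the Cell Ranger versions of the file headers, the melanocyte-like share was 0.0345% in lesional against 2.83% in healthy libraries for version 7.1.0 (n = 3 each, exact p = 0.1, the smallest possible) and 0% against 0.771% for version 7.2.0 (n = 3 each, exact p = 0.4). T/NK-like cells made up 7.0% ± 6.50 of lesional and 4.50% ± 2.90 of healthy cells, a difference smaller than the spread between libraries (n = 6 each, exact p = 0.411, adjusted 0.754). It was 2.50 points, and 0.608 without lesional replicate 4. Myeloid-like cells stood at 3.33% ± 2.46 and 1.70% ± 0.777 (n = 6 each, exact p = 0.162, adjusted 0.446). Lymphatic endothelial-like cells were at 3.87% ± 1.87 in lesional and 1.71% ± 0.739 in healthy libraries (n = 6 each), with an exact p of 0.0238 that did not pass the adjustment (0.131). Without lesional replicate 2 the adjusted p was 0.0238 (difference 2.68 points against 2.16).

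In vascular endothelial cells of lesional skin, the genes of the interferon gamma response were higher than in healthy skin relative to the other genes of these cells. Of 21 tested members 19 had estimates above 0, with a median log2 fold change of 0.37 (camera adjusted p = 2.88e-09, adjusted p = 0.557 with an estimated correlation). The mean makeup of the class differed in part. A cluster led by KIF5C held 11.6% ± 3.23 of lesional, 8.52% ± 4.05 of nonlesional and 6.31% ± 3.52 of healthy endothelial cells (n = 6, 5 and 6). Neither this makeup nor levels within single clusters were tested. GBP2, a guanylate-binding protein induced by interferon, stood at 143 ± 50.1 CPM in lesional and 95.6 ± 15.4 in healthy libraries (log2 fold change 0.59, SE 0.217, n = 6 each). GBP1 was at 108 ± 59.4 and 54.6 ± 18.1 (1.04, SE 0.385). CXCL9, which draws T cells through the receptor CXCR3, was at 67.4 ± 121 CPM in lesional and 0.230 ± 0.387 in healthy libraries, above the healthy mean in 4 of 6 lesional libraries. The genes of MHC class II presentation, which display antigen to helper T cells, were also higher in this class, with 10 of 10 estimates above 0 and a median of 0.35 (adjusted p = 6.08e-06, adjusted p = 0.605 with an estimated correlation). Among them CTSS, a protease of that pathway, was at 36.4 ± 9.65 against 20.9 ± 5.62 CPM (0.88, SE 0.223, higher in 6 of 6). It was the 1 member called when adjusted over the list alone. Without lesional replicate 4 the median of the class II list was 0.18. MHC class I genes had 10 of 11 estimates above 0 and a median of 0.15 (adjusted p = 0.0219, adjusted p = 0.635 with an estimated correlation). HLA-B was at 5161 ± 969.9 against 4311 ± 788.5 CPM. The type I interferon list in these cells was not called (median 0.11, adjusted p = 0.208). Keratinocyte markers had 6 of 8 estimates above 0 and a median of 0.30 (adjusted p = 0.0307, adjusted p = 0.726 with an estimated correlation). This median was not stable: it was -0.20 without lesional replicate 3, 1.19 without healthy replicate 5 and -0.16 with the Cell Ranger version as a term. The summed level of the immune cell markers in the endothelial sums was 149 ± 41.5 CPM in lesional and 166 ± 57.5 in healthy libraries.

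In lesional fibroblasts, HES1, a transcriptional repressor downstream of Notch signalling, was lower in the sums over all fibroblast clusters (ENSG00000114315, GRCh38 chromosome 3, 194136145 to 194138732, plus strand). It stood at 82.5 ± 21.1 CPM in lesional and 195 ± 48.8 in healthy fibroblasts (log2 fold change -1.29, SE 0.22, adjusted p = 0.0278, n = 6 each) and was lower than the healthy mean in 6 of 6 lesional libraries. The mean makeup of the class differed too, by less than the larger SD. A cluster led by APOD held 15.8% ± 2.88 of lesional and 29.3% ± 20.9 of healthy fibroblasts. One led by WIF1 and COMP held 27.7% ± 14.9 and 14.5% ± 17.6 (n = 6 each). Neither this makeup nor levels within single clusters were tested. The interferon gamma response list was higher, with 10 of 13 estimates above 0 and a median of 0.31 (adjusted p = 0.01, adjusted p = 0.635 with an estimated correlation). 3 members were called when adjusted over the list alone. Among them SOCS1, an inhibitor of interferon signalling, was at 56.4 ± 14.4 against 25.8 ± 8.83 CPM (0.99, SE 0.303). It was above the healthy mean in 6 of 6 libraries. MHC class II genes had 7 of 7 estimates above 0 and a median of 1.62 (adjusted p = 0.00543, adjusted p = 0.635 with an estimated correlation). HLA-DRA was at 114 ± 109.5 against 24.9 ± 24.2 CPM. With doublets removed at the expected rate the class II list was not called (median 1.43, adjusted p = 0.0565). Keratinocyte markers were higher in the same sums (7 of 7 above 0, median 1.43, adjusted p = 0.00332, adjusted p = 0.605 with an estimated correlation). KRT5, a basal keratin, was at 58.1 ± 68.2 against 11.4 ± 18.7 CPM. Ribosomal protein genes were higher as well (30 of 30 above 0, median 0.23, adjusted p = 0.000491, adjusted p = 0.827 with an estimated correlation). Extracellular matrix genes were not called (median 0.04, adjusted p = 0.769), and CXCL12, a chemokine of dermal fibroblasts, was at 1389 ± 747.4 and 1831 ± 401.2 CPM (-0.41, SE 0.301).

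In lesional keratinocytes, DLK2, a Delta-like ligand related to the Notch ligands, rose (ENSG00000171462, GRCh38 chromosome 6, 43450352 to 43456632, minus strand). It stood at 35.4 ± 12.5 CPM in lesional (n = 6) and 7.46 ± 3.69 in healthy keratinocytes (n = 4). This was 4.38-fold by the fit (log2 fold change 2.13, SE 0.327, adjusted p = 0.0397). It lay above the healthy mean in 6 of 6 libraries. Basal adhesion genes were higher (11 of 14 above 0, median 0.38, adjusted p = 0.000283, adjusted p = 0.557 with an estimated correlation). LAMA3, a laminin chain of the basement membrane, was at 112 ± 45.4 against 48.4 ± 16.7 CPM. The mean makeup of the class differed as well. A cluster led by SYT8, LAMB4 and COL17A1 held 27.1% ± 12.9 of lesional (n = 6), 22.2% ± 7.15 of nonlesional (n = 4) and 14.0% ± 6.67 of healthy keratinocytes (n = 4). One led by KRT2 held 22.9% ± 5.52, 30.3% ± 9.32 and 36.4% ± 13.3. The sums are over all clusters of the class, and neither this makeup nor levels within single clusters were tested. Terminal differentiation genes were higher too (8 of 10 above 0, median 0.27, adjusted p = 0.0254, adjusted p = 0.605 with an estimated correlation). KLK5, a protease of the outer epidermis, was at 62.9 ± 26.3 against 8.41 ± 9.83. KRT2 was at 1107 ± 472.6 against 297 ± 193 CPM. MHC class II genes had 7 of 8 estimates above 0 and a median of 1.47 (adjusted p = 0.00279, adjusted p = 0.635 with an estimated correlation). The markers of immune cells had fewer than 4 tested genes in keratinocyte and fibroblast sums, so no list test of immune RNA could be run beside the class II lists. The interferon gamma list of keratinocytes was not called (median -0.07, adjusted p = 0.753). Pigmentation genes, which are mostly genes of melanocytes, were lower in these sums (4 of 5 below 0, median -0.59, adjusted p = 0.00919, adjusted p = 0.402 with an estimated correlation). The melanocyte-like share of the lesional libraries was lower as well (0.0172% against 1.80%), and RNA of melanocytes in the sums was not set apart. Without healthy replicate 6 the median was -0.34. GPNMB was at 204 ± 7.89 against 306 ± 98.0. KIT was at 2.64 ± 1.56 against 9.94 ± 12.1 CPM (log2 fold change -1.98, and -0.17 without healthy replicate 6). Immediate early and heat shock genes were lower (0 of 20 above 0, median -0.95, adjusted p = 6.08e-06, adjusted p = 0.649 with an estimated correlation). So were mitochondrially encoded genes (0 of 12, median -0.43, adjusted p = 5.05e-05, adjusted p = 0.632 with an estimated correlation). Ribosomal protein genes were higher (30 of 30, median 0.33, adjusted p = 6.08e-06, adjusted p = 0.702 with an estimated correlation).

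In lesional T/NK cells the interferon gamma response list was higher (9 of 11 above 0, median 0.15, adjusted p = 0.00596, adjusted p = 0.557 with an estimated correlation). The median was from 0.08 without lesional replicate 1 to 0.34 without lesional replicate 3. GBP2 was at 137 ± 80.8 against 63.7 ± 21.3 CPM (log2 fold change 0.79, SE 0.409, n = 5 each). Keratinocyte markers were higher in the same sums (5 of 5, median 1.48, adjusted p = 0.000646, adjusted p = 0.402 with an estimated correlation). KRT5 was at 131 ± 57.3 against 20.6 ± 24.0 CPM. The median of the markers was 0.59 without lesional replicate 3 and 2.94 without healthy replicate 4. Neither the Th1 list (median -0.15, adjusted p = 0.251) nor the cytotoxic list (median -0.04, adjusted p = 0.251) was called. IFNG, the interferon gamma gene, was at 109 ± 85.9 and 146 ± 225 CPM (-0.45, SE 1.08), a change that turned to 0.97 without healthy replicate 4 and to 1.26 with voom. GZMK, a granzyme of memory T cells, was at 243 ± 78.0 and 92.5 ± 78.4 (1.32, SE 0.549), and neither passed the test. The Th2 genes had too few tested members for a list test, and IL13 gave 10 UMIs in lesional T/NK cells (4.79 CPM of the pooled UMIs) and 26 in healthy ones (49.3 CPM), of which 24 came from 1 library.

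By edgeR, 1 of 11392 genes was called in keratinocytes (410 higher and 431 lower at an unadjusted p under 0.05), 1 of 7799 in fibroblasts (186 and 234), 0 of 2789 in T/NK cells (39 and 50) and 0 of 10376 in endothelial cells (147 and 177). DESeq2 called 32, 1, 0 and 0. The DLK2 call was lost without lesional replicates 2, 3, 4 or 6 or healthy replicates 4, 5 or 6 (log2 fold changes from 1.82 to 2.52 over all leave-outs). It was also lost with only the 2 groups compared, a 10% mitochondrial limit, only the 7.1.0 libraries and voom. That of HES1 was lost without lesional replicates 1, 2, 3, 5 or 6 or healthy replicates 2 or 6 (from -1.42 to -1.17), with sums of at least 50 cells, with a 10% mitochondrial limit and within each Cell Ranger version. Of 56 list and class pairs 17 were called (14 higher and 3 lower), and 0 with an estimated correlation (smallest adjusted p = 0.402). In 14 lists 21 members were called when adjusted over the list alone. The fibroblast interferon gamma call ended without healthy replicates 1 or 2 (medians 0.17 and 0.18) or lesional replicate 4. That of T/NK cells ended without lesional replicates 1 or 2 or healthy replicate 2. The class II calls ended without healthy replicate 6 in keratinocytes and without healthy replicate 1 or lesional replicate 1 in fibroblasts. With only the 7.1.0 libraries, the keratinocyte class II list (median 1.24, adjusted p = 0.122) and heat shock genes (-0.31, adjusted p = 0.234) were not called. The endothelial class I call ended without healthy replicates 1, 2, 3 or 5 or lesional replicates 1, 2 or 4, and the keratinocyte markers there without healthy replicates 1, 2 or 3 or lesional replicates 3 or 4. Terminal differentiation was not called without healthy replicate 1 (median 0.24), with the Cell Ranger version as a term (0.25, adjusted p = 0.0533) or with no filter on low counts (0.71, adjusted p = 0.0518), and its median was from 0.11 without lesional replicate 4 to 1.42 without healthy replicate 4. Heat shock genes were not called without healthy replicate 5 (-0.52), and fibroblast ribosomal genes without healthy replicates 3 or 5 or lesional replicate 4 (medians 0.13, 0.08 and 0.07).

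Nonlesional against healthy skin asks whether unaffected skin of donors with vitiligo differs from healthy skin. Melanocyte-like cells were present in nonlesional skin, at 3.03% ± 3.54 of cells (n = 5) against 1.80% ± 1.97 in healthy skin (n = 6, exact p = 0.522, adjusted 0.917). Pooled, 236 of 6028 nonlesional cells were of this class (3.92%, Clopper-Pearson interval 3.44 to 4.44%), in 4 of 5 libraries, and nonlesional replicate 1 had none, which allows up to 1.53%. Of the 236 cells 147 were in nonlesional replicate 2, and without it the difference of 1.23 percentage points turned to -0.24. Lymphatic endothelial-like cells were at 5.49% ± 5.04 (n = 5) and 1.71% ± 0.739 (n = 6), exact p = 0.00866 and 0.0952 after adjustment. The difference of 3.77 points was 1.57 without nonlesional replicate 1. T/NK-like cells were at 5.37% ± 3.71 and 4.50% ± 2.90 (n = 5 and 6, exact p = 0.667, adjusted 0.917), a difference that turned to -0.311 points without nonlesional replicate 3. Within the Cell Ranger versions, the lymphatic share was 3.40% against 1.97% for version 7.1.0 (n = 2 and 3, exact p = 0.3) and 6.87% against 1.46% for version 7.2.0 (n = 3 each, exact p = 0.1, the smallest possible).

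Endothelial cells of nonlesional skin had higher levels of the interferon gamma list (20 of 21 above 0, median log2 fold change 0.28, adjusted p = 0.000427, adjusted p = 0.851 with an estimated correlation) and of MHC class II genes (10 of 10, median 0.42, adjusted p = 0.000105, adjusted p = 0.851 with an estimated correlation). The same libraries were also split in other ways into groups of the same sizes (40 splits, the real one included). Of these splits 8 gave a -log10 p of the interferon gamma list as large as the real 4.418, and the highest other gave 8.408. Chance can thus not be excluded for this list. IRF1, a transcription factor of the interferon response, was at 159 ± 91.6 CPM in nonlesional (n = 5) and 93.9 ± 32.2 in healthy libraries (n = 6; log2 fold change 0.80, SE 0.36). CTSS was at 32.5 ± 10.3 and 20.9 ± 5.62 (0.68, SE 0.243, higher in 5 of 5). Keratinocyte markers had 8 of 8 estimates above 0 in these sums (median 0.34) and were not called (adjusted p = 0.259). Both endothelial calls were lost without nonlesional replicate 3, where the median was 0.17 for the interferon gamma list and 0.04 for class II. Of the members, CTSS (0.66) and HLA-DQB1 (0.68 against 0.85 with all libraries) stayed higher without it.

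In nonlesional keratinocytes the MHC class I and interferon lists were lower than in healthy ones (n = 4 each). MHC class I genes had 1 of 11 estimates above 0 (median -0.35, adjusted p = 0.000405, adjusted p = 0.757 with an estimated correlation). Type I interferon genes had 2 of 11 (median -0.71, adjusted p = 0.00448, adjusted p = 0.851 with an estimated correlation). Interferon gamma genes had 0 of 12 (median -0.27, adjusted p = 0.0099, adjusted p = 0.851 with an estimated correlation). HLA-C was at 332 ± 121 against 549 ± 82.5 CPM (-0.73, SE 0.263). PSMB9, an immunoproteasome subunit, was at 45.1 ± 13.4 against 87.0 ± 30.4 (-0.85, SE 0.339). IFI6 was at 2.28 ± 1.43 against 14.3 ± 11.5 (-2.34, SE 0.742). Each of the 3 was below the healthy mean in 4 of 4 libraries. MHC class II genes were not called (6 of 8 above 0, median 0.28, adjusted p = 0.66). Terminal differentiation genes were higher (9 of 10 above 0, median 0.99, adjusted p = 0.000381, adjusted p = 0.757 with an estimated correlation, 2 members called when adjusted over the list alone). The median of this list was from 0.15 to 1.71 over the alternatives. TGM3, a transglutaminase of the cornified envelope, was at 16.2 ± 4.52 against 4.62 ± 3.17 CPM. Ribosomal protein genes were lower by little (2 of 30 above 0, median -0.11, adjusted p = 0.0115, adjusted p = 0.895 with an estimated correlation), and this direction turned with a 10% mitochondrial limit. The class I median was -0.13 without nonlesional replicate 4. The interferon gamma call was lost without healthy replicates 4 or 5 (median -0.10 without the latter) or nonlesional replicate 4, and the type I interferon call without healthy replicate 5 (-0.36) or with only the clusters that have a marker among their 10 leading genes (median -0.46, adjusted p = 0.267). With only the 7.1.0 libraries none of these 4 lists was called, at medians of -0.25 for interferon gamma, -0.29 for type I interferon, -0.12 for class I and 0.15 for terminal differentiation.

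In nonlesional fibroblasts the keratinocyte markers were higher (7 of 7 above 0, median 1.80 and from 1.15 to 2.45 over the alternatives, adjusted p = 0.000105, adjusted p = 0.757 with an estimated correlation). So were ribosomal protein genes (30 of 30, median 0.26, adjusted p = 0.00384, adjusted p = 0.895 with an estimated correlation), whose median turned to -0.11 without nonlesional replicate 3. The interferon gamma list (median 0.34, adjusted p = 0.11) and MHC class II list (median 1.54, adjusted p = 0.259) were not called there. In T/NK cells mitochondrially encoded genes (11 of 12, median 0.34, adjusted p = 0.00181, adjusted p = 0.895 with an estimated correlation) and keratinocyte markers (4 of 5, median 1.22, adjusted p = 0.0309, adjusted p = 0.757 with an estimated correlation) were higher. The cytotoxic list (median 0.21, adjusted p = 0.0648), the regulatory T cell list (median -0.51, adjusted p = 0.0648) and the Th1 list (median 0.02, adjusted p = 0.351) were not called. CXCR3 was at 129 ± 69.8 CPM in nonlesional (n = 4) and 61 ± 42.5 in healthy T/NK cells (n = 5; log2 fold change 1.21, SE 0.537).

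No gene was called by edgeR in keratinocytes (273 higher and 223 lower at an unadjusted p under 0.05), T/NK cells (40 and 56), fibroblasts (134 and 195) or endothelial cells (132 and 145). DESeq2 called 2 in T/NK cells and 0 in the others. Of 56 list and class pairs 11 were called (7 higher and 4 lower), and 0 with an estimated correlation (smallest adjusted p = 0.757). In 5 lists 6 members were called when adjusted over the list alone. Without healthy replicate 6, 19 pairs were called. The ribosomal calls ended in keratinocytes without healthy replicates 1 or 4 or nonlesional replicate 4, and in fibroblasts without healthy replicates 3 or 5 or nonlesional replicate 3. In T/NK cells the mitochondrial call ended without healthy replicates 1 or 2 or nonlesional replicate 4, and that of the keratinocyte markers without healthy replicates 1, 2 or 5 or nonlesional replicates 2, 3 or 4.

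Lesional against nonlesional skin asks what sets affected skin apart from unaffected skin of donors with the disease. The melanocyte-like share was 0.0172% ± 0.0273 in lesional (n = 6) and 3.03% ± 3.54 in nonlesional libraries (n = 5), exact p = 0.0152 and adjusted 0.167. In the 5 donors with both kinds of skin, it was lower in lesional skin in 4 and higher in 0, with a mean difference of -3.01 percentage points ± 3.52 (exact sign-flip p = 0.125, the smallest that 4 differing pairs can give, adjusted 0.688). The difference between the group means was -3.01 points as well, and -1.54 without nonlesional replicate 2. Per 100 keratinocyte-like and melanocyte-like cells, the lesional libraries held 0.0694 ± 0.121 (n = 6) and the nonlesional ones 15.8 ± 9.50 (n = 4, exact p = 0.00476, the smallest possible with the libraries taken as independent). The nonlesional library with no melanocyte-like cell held too few of these cells for this measure and was left out, so the p depends on its absence. This measure was not tested with the donors paired. The T/NK-like share was 7.0% ± 6.50 against 5.37% ± 3.71 (n = 6 and 5, exact p = 0.639, adjusted 0.976), a difference that turned to -0.265 points without lesional replicate 4. Within the Cell Ranger versions, the melanocyte-like share was 0.0345% against 5.37% for version 7.1.0 (n = 3 and 2, exact p = 0.1, the smallest possible) and 0% against 1.47% for version 7.2.0 (n = 3 each, exact p = 0.4).

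In the unpaired fit, keratinocyte sums of lesional skin had higher levels of antigen presentation genes than those of nonlesional skin (n = 6 and 4). MHC class I genes had 11 of 11 estimates above 0 (median log2 fold change 0.23, adjusted p = 0.0166), MHC class II genes 8 of 8 (median 1.03, adjusted p = 0.0149) and interferon gamma genes 10 of 12 (median 0.31, adjusted p = 0.0452). With the donor as a block (4 pairs) the class I (median 0.20, adjusted p = 0.0752) and interferon gamma lists (0.14, adjusted p = 0.345) were not called, and class II was (1.51). Under that block HLA-DPB1 was called together with FCGBP, S100B and HLA-DQB2, named after their values were seen, which are on the fixed list of Langerhans cell genes. With only the clusters that have a marker among their 10 leading genes class II was not called (0.35, adjusted p = 0.391), so RNA of Langerhans cells in these sums was not set apart from a change of keratinocytes. PSMB8, an immunoproteasome subunit, was at 105 ± 36.8 against 60.0 ± 20.3 CPM (0.80, SE 0.279). HLA-C was at 484 ± 109.5 against 332 ± 121 (0.54, SE 0.242). HLA-DPB1 was at 34.1 ± 18.8 against 13.2 ± 7.90 (1.34, SE 0.589). Basal adhesion genes (14 of 14, median 0.34, adjusted p = 0.00604), cell cycle genes (15 of 16, median 0.34, adjusted p = 0.0365) and ribosomal protein genes (30 of 30, median 0.44, adjusted p = 2.16e-14) were higher too. ITGB1, an integrin of basal cells, was at 149 ± 22.7 against 104 ± 9.36 CPM. MCM2, a DNA replication factor, was at 18.7 ± 5.19 against 9.82 ± 2.57. Mitochondrially encoded genes (0 of 12 above 0, median -0.52, adjusted p = 9.68e-08) and immediate early and heat shock genes (0 of 20, median -0.59, adjusted p = 0.00276) were lower. The median of the last list was 0.00182 without nonlesional replicate 5 and 0.11 with only the 7.1.0 libraries, so its direction did not hold there. For each of these lists the adjusted p was 0.932 with an estimated correlation.

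In lesional T/NK cells the interferon gamma list was higher than in nonlesional ones (10 of 11 above 0, median 0.29, adjusted p = 0.00104), and so was the regulatory T cell list (6 of 7, median 0.32, adjusted p = 0.0166), each with an adjusted p = 0.932 with an estimated correlation. Over the alternatives the median of the interferon gamma list was from 0.08 to 0.64. The median of the regulatory T cell list turned to -0.16 with sums of at least 50 cells and to -0.08 with the donor as a block, and neither list was called in these 2 settings. GBP5 was at 162 ± 99.3 against 64.0 ± 22.7 CPM (log2 fold change 0.96, SE 0.454). ICOS, a costimulatory receptor, was at 188 ± 73.7 against 99.0 ± 32.9 (0.90, SE 0.346, n = 5 and 4). The Th1 list (median -0.13, adjusted p = 0.963) and the cytotoxic list (median -0.27, adjusted p = 0.41) were not called. FOXP3, the factor of regulatory T cells, gave 47 UMIs in lesional, 17 in nonlesional and 14 in healthy T/NK cells, which is 22.5, 20.8 and 26.6 CPM of the pooled UMIs. Keratinocyte markers had 5 of 5 estimates above 0 in these sums (median 0.49), and the list was not called.

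In lesional myeloid cells MHC class II genes (1 of 10 above 0, median -0.36, adjusted p = 0.0368) and ribosomal protein genes (0 of 30, median -0.27, adjusted p = 0.00283) were lower than in nonlesional ones in the unpaired fit (n = 4 and 3, adjusted p = 0.932 for each with an estimated correlation). With the donor as a block (2 pairs) neither was called, and the ribosomal median turned to 0.10, as it did with only the 7.1.0 libraries (0.11). HLA-DRB1 was at 9654 ± 2896 against 13660 ± 1471 CPM. Keratinocyte markers had 5 of 5 estimates above 0 in these sums (median 1.32), and the list was not called. CCL18, a chemokine of macrophages and dendritic cells, gave 227 UMIs in lesional myeloid cells, of which 186 came from 1 library, and 0 in nonlesional ones. Over the limit for the pooled group this is at least 26.6-fold higher, a bound that covers counting error and not the spread between donors. By edgeR on the library sums CCL18 was not called. CXCL9 gave 47 UMIs in 4 of 6 lesional libraries and 0 in healthy and in nonlesional ones, at least 3.03-fold and 5.51-fold higher over limits of the same kind. CXCL10 gave 41 UMIs in lesional myeloid cells (24.4 CPM of the pooled UMIs), of which 36 came from 1 library, 8 in nonlesional (13.6 CPM) and 0 in healthy ones. In fibroblasts mitochondrially encoded genes were lower (1 of 12 above 0, median -0.28, adjusted p = 0.00604, adjusted p = 0.932 with an estimated correlation). Their median was from -0.38 to -0.12 over the alternatives. In endothelial cells the interferon gamma list was at a median of 0.09 and was not called (adjusted p = 0.0587).

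By edgeR no gene was called in keratinocytes (480 higher and 246 lower at an unadjusted p under 0.05), T/NK cells (36 and 11), myeloid cells (99 and 75), fibroblasts (39 and 19) or endothelial cells (64 and 70). DESeq2 called 19 in keratinocytes and 0 in the others. With the donor as a block, which fits the labels' pairing, edgeR called 5 genes in keratinocytes (4 pairs), 4 in fibroblasts (4 pairs) and 89 in myeloid cells (2 pairs). The fifth keratinocyte gene, beside the 4 named above, was ACKR1, also named after its values were seen. Among the leading ones of the 89 were COL3A1, COL1A2 and AQP1, which are genes of fibroblasts and vessels. Of 70 list and class pairs 13 were called (8 higher and 5 lower), and 0 with an estimated correlation. In the lists 1 member was called when adjusted over the list alone. The block gave 19 of 72 pairs, of which 7 were among the 13. It ended the interferon gamma and class I calls in keratinocytes, those of both lists in T/NK cells and those of both lists in myeloid cells. Without nonlesional replicate 3, 27 pairs were called. The keratinocyte interferon gamma call was lost without lesional replicates 1, 2, 3 or 4 or nonlesional replicates 2, 4 or 5, and that of T/NK cells without lesional replicate 1. The keratinocyte class I call ended without lesional replicates 1 or 4 or nonlesional replicate 4 (medians 0.20, 0.14 and 0.09, and 0.43 without nonlesional replicate 3), and the class II call without lesional replicate 4 or nonlesional replicates 4 or 5. Cell cycle genes were not called without lesional replicates 3 or 5 or nonlesional replicates 2 or 4, adhesion genes without nonlesional replicate 2, and heat shock genes without nonlesional replicate 5. Adhesion genes had a median of 0.19 without nonlesional replicate 2, and cell cycle genes one of 0.11 without lesional replicate 5. The regulatory T cell call ended without lesional replicates 2 or 3 or nonlesional replicates 2, 3, 4 or 5. The myeloid class II call ended without lesional replicates 3 or 5 or nonlesional replicate 2, the myeloid ribosomal call without lesional replicates 1 or 5 or nonlesional replicates 3 or 5, and the fibroblast mitochondrial call without lesional replicate 3 or nonlesional replicates 3 or 4.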

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

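Of the tests given here, the count of melanocyte-like cells per 100 keratinocyte-like and melanocyte-like cells, the fits by Cell Ranger version and the removal of doublets at the expected rate were chosen only after the results were seen. Melanocyte-like cells were close to absent from lesional libraries. Lesional melanocytes clustered with other cells would leave cells with melanocyte genes elsewhere, but the lesional share of cells with UMIs of at least 3 of 5 melanocyte genes was 0.525% of the nonlesional share (exact p = 0.0152), with 3 such cells in lesional, 249 in nonlesional and 92 in healthy skin. These 5 genes are also among the markers that named the class, so melanocytes with low levels of them would be missed by both counts. Less epidermis in the lesional libraries would leave the number per epidermal cell alike. In the libraries measured, that number differed by -15.8 per 100 between lesional and nonlesional skin (exact p = 0.00476). The nonlesional library with no melanocyte-like cell held too few epidermal cells and was left out, so this p depends on its absence. Less epidermis was thus checked only among libraries with enough of these cells. Both exact tests took the libraries as independent, although 5 donors gave both kinds of skin, so their p-values are uncertain. Neither measure was tested with the donors paired. Loss of melanocytes from the lesions may account for the pattern, and a lower yield of these cells from lesional skin during digestion was not tested.

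Interferon gamma response genes were higher in lesional than in healthy endothelial sums, with a median log2 fold change of 0.37. RNA of immune cells in these sums would raise their markers, whose summed level differed by -0.13 on the log2 scale (exact p = 0.606), and with the Cell Ranger version as a term or within 1 version the lowest median was 0.37. With each library left out in turn the lowest median was 0.33, so no single library carries it. Among 40 splits of the same libraries into groups of the same sizes, the real one included, 3 gave a -log10 p of the list as large as the real 10.29, and the highest other split gave 12.5, so chance cannot be excluded. An interferon response of the lesional endothelium is one possible explanation, and interferon signalling itself was not measured.

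Keratinocyte markers were higher in fibroblast sums of both vitiligo groups than in healthy ones. Across 16 libraries their level in fibroblasts rose with the keratinocyte share of UMIs (Spearman rho = 0.621, permutation p = 0.0116; Pearson r = 0.624, permutation p = 0.0102), a trend across all libraries that free keratinocyte RNA in the droplets would give. These permutations took the libraries as independent, although 4 donors gave both a lesional and a nonlesional one. Without the 2 libraries farthest from the median r was 0.415, and within the versions rho was 0.5 for 7.1.0 (exact p = 0.216) and 0.571 for 7.2.0 (exact p = 0.151), n = 8 each. Within the groups (n = 6 each) rho was 0.771 in healthy (exact p = 0.103; r = 0.885, and 0.0841 without the 2 farthest) and 0.371 in lesional libraries (exact p = 0.497; r = 0.505, and -0.114 without the 2 farthest). The relation thus rests on few libraries and is weak within the lesional group, so free RNA stays a possible explanation only. The keratinocyte share of UMIs was 13.5 to 33.9% in the nonlesional libraries used, within the healthy range of 0.703 to 52.2%. Whether the trend accounts for the difference between the groups was not tested. With doublets removed at the expected rate the median of the markers, nonlesional against healthy, was 1.19 against 1.80 before, and doublets that such removal misses cannot be told apart from free RNA. A biological source, such as keratin expression by fibroblasts, was not tested.

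In other splits of the same libraries into groups of the same sizes, 40 per comparison with the real one included, as many calls as in the real split were found as follows. For lesional against healthy keratinocytes (1 gene called) 4 splits gave as many. The highest other split gave 105, and no further split gave more than 1. Whether that 1 split reflects a structure of the samples other than the groups was not tested. Of the keratinocyte sums used, 3 of 4 healthy and 3 of 6 lesional ones were of version 7.1.0. For lesional against healthy fibroblasts (1 gene) it was 2 splits, with 1 as the highest other. In the comparisons with 0 genes called all 40 splits must give as many, so that count decides nothing there. The highest others were 6 in T/NK and 0 in endothelial cells for lesional against healthy skin. They were 0 in keratinocytes, 4 in T/NK cells, 5 in fibroblasts and 21 in endothelial cells for nonlesional against healthy skin. For lesional against nonlesional skin they were 22 in keratinocytes, 24 in T/NK cells, 8 in myeloid cells, 2 in fibroblasts and 6 in endothelial cells, over drawn splits of which some leave donors whole on one side. In the 24 splits that part each donor pair the highest others were 3, 0, 8, 0 and 0. The list calls were met or passed by 7 of 40 splits for lesional against healthy (17 called, highest other 27), by 32 for nonlesional against healthy (11, highest 25) and by 37 for lesional against nonlesional skin (13, highest 30). Of the 24 splits that part each donor pair, 19 gave as many list calls as the real 13 (highest other 24). Chance can be excluded for none of the counts above 0.

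A single library stood far from the rest of its group in 2 of 30 share groups and in 30 of 299 gene groups (10.0%). Chance marks about 1 in 20 where the values are normally distributed. Genes of low counts need not be, so the 10.0% cannot be read as an excess over that rate. Each value below is the gap of the extreme library to its nearest neighbour divided by the range of the group. In lymphatic endothelial shares it was 0.642 for the lowest healthy and 0.783 for the highest nonlesional library. In lesional keratinocytes the lowest library stood apart for HLA-DQB1 (0.814), KRT2 (0.668) and MCM5 (0.70), and the highest for KRT6A (0.804). In healthy keratinocytes the highest library stood apart for HLA-DQA1 (1.0), HLA-E (0.856), HLA-DPA1 (0.863) and ITGB1 (0.851), and the lowest for TGM3 (0.877) and RPS27 (0.86). In nonlesional keratinocytes the lowest stood apart for POSTN (0.876), KIT (0.876), RPL3 (0.854) and RPLP0 (0.851), and the highest for HSPA1A (0.881). In T/NK cells it was the lowest healthy library for GZMK (0.764), the lowest nonlesional for GBP2 (0.861), the highest nonlesional for MT-CYB (0.942) and the lowest lesional for KRT14 (0.732). In fibroblasts it was the lowest healthy library for MT-ND4 (0.732), MT-ATP6 (0.846) and MT-ND2 (0.747), the highest healthy for CXCL12 (0.771), the highest nonlesional for HLA-DRA (0.857) and RPL13A (0.853), and the lowest lesional for SOCS1 (0.689). In endothelial cells it was the highest nonlesional library for TAPBP (0.788), the highest healthy for CXCL10 (0.824) and the lowest lesional for PERP (0.735) and IRF1 (0.749).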

How the results depend on the processing

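The alternatives by Cell Ranger version, voom, expected-rate doublets, keratinocyte core clusters, looser sums and melanocytes per epidermal cell were added after the data were seen. Of the values that answer a comparison, 407 stayed the same under an alternative, 76 moved and 3 became stronger. Of the named genes and lists, 4917 values stayed the same, 248 lost their call, 13 gained one and 37 turned direction. The cause was not tested except where fewer libraries or genes were used. Counts of genes past the threshold were small or 0, so most of the moves are by a few genes. No fit could be had for T/NK cells against healthy skin from sums of at least 50 cells, for keratinocytes against healthy skin or myeloid cells within version 7.2.0, for myeloid cells under the 10% mitochondrial limit, or for list tests in DESeq2 and voom. At this depth the melanocyte comparison rests on counts of cells, not on gene levels.

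With DESeq2, 32 keratinocyte genes (lesional against healthy), 19 keratinocyte genes (lesional against nonlesional) and 2 T/NK genes (nonlesional against healthy) were called. With RLE size factors the last count was 2 as well. With no filter on low counts, the counts were 5 in keratinocytes, 27 in T/NK cells and 30 in fibroblasts for lesional against healthy, 3 in T/NK cells and 5 in fibroblasts for nonlesional against healthy, and 2 in keratinocytes, 7 in T/NK cells, 23 in myeloid cells and 1 in fibroblasts for lesional against nonlesional skin. With sums of at least 50 cells they were 5 in keratinocytes and 0 in fibroblasts (lesional against healthy) and 6 in myeloid cells. With only the 2 groups compared they were 0 in keratinocytes (lesional against healthy), 1 in T/NK cells (nonlesional against healthy) and 1 in myeloid cells. With a 10% mitochondrial limit they were 2 in T/NK cells (nonlesional against healthy) and 0 in fibroblasts (lesional against healthy). That limit turned S100A8 in keratinocytes (0.41, nonlesional against healthy) and the ribosomal protein genes list in keratinocyte, nonlesional versus healthy (0.0516). The cause was not tested.

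With the Cell Ranger version as a term, the counts were 4 in keratinocytes (lesional against healthy), 1 in keratinocytes and 1 in T/NK cells (nonlesional against healthy). With only the 7.1.0 libraries they were 0 in keratinocytes and 0 in fibroblasts (lesional against healthy), 1 in T/NK cells (nonlesional against healthy) and 7 in myeloid cells. With those libraries, lesional against healthy, S100A8 in keratinocytes turned to 0.54 and GBP5 in T/NK cells to -0.29. The value was -0.0122 for CCL5 in T/NK, lesional versus healthy, and -0.0197 for CXCR3 in T/NK, lesional versus healthy. Nonlesional against healthy, S100A8 turned to 1.23 and KRT6A to -0.78. It was 0.00801 for HSPA6 in keratinocyte, lesional versus nonlesional, 0.0746 for RPL27 in myeloid, lesional versus nonlesional, and 0.11 for the ribosomal protein list of myeloid cells. With only the 7.2.0 libraries the counts were 3 in T/NK cells and 4 in fibroblasts (lesional against healthy), 4 in T/NK cells and 5 in fibroblasts (nonlesional against healthy), and 1 in keratinocytes and 1 in T/NK cells (lesional against nonlesional), and the list calls were 7 (nonlesional against healthy) and 21 (lesional against nonlesional). With those libraries GZMB turned to 0.58 (lesional against healthy), and GZMK in T/NK, nonlesional versus healthy, to -0.0386. They turned KRT6A in keratinocytes to -0.64, CCL5 to 0.70 and CXCR3 to 1.04, lesional against nonlesional. The value was -0.39 for TNFRSF18 in T/NK, lesional versus nonlesional, and -1.5 for CCL2 in fibroblast, lesional versus nonlesional. Each version holds 2 or 3 libraries per group.

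With voom the counts were 0 in keratinocytes and 1 in T/NK cells (lesional against healthy) and 1 in T/NK cells (nonlesional against healthy). It turned S100A8 in keratinocytes (nonlesional against healthy) to 0.33, IFNG to 1.26 (lesional against healthy) and 1.82 (nonlesional against healthy), and GZMB to 0.50 (lesional against healthy). With the keratinocyte clusters that have a marker among their 10 leading genes, the counts were 10 (lesional against healthy) and 1 (lesional against nonlesional), and KRT16 turned to -0.34 (nonlesional against healthy) and 0.34 (lesional against nonlesional). Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons, and fry called 0, 0 and 0. The melanocyte difference per 100 keratinocyte-like and melanocyte-like cells was -16.4 (lesional against healthy) and -15.8 (lesional against nonlesional). The cause of these moves was not tested.

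Each list call was lost by camera with an estimated correlation and by fry. Other settings ended these calls. Lesional against healthy, the 7.1.0 libraries alone ended class II and heat shock genes in keratinocytes, interferon gamma and keratinocyte markers in T/NK cells, ribosomal genes in fibroblasts, and class I and II in endothelial cells. The 7.2.0 libraries alone ended interferon gamma in fibroblasts, fits of only the 2 groups ended it in T/NK cells, sums of at least 50 cells ended ribosomal genes in fibroblasts, and the 10% mitochondrial limit ended keratinocyte markers in endothelial cells. Removal of doublets at the expected rate ended class II in fibroblasts, the marker-led clusters ended ribosomal genes in keratinocytes, and the version term or no filter on low counts ended terminal differentiation. Nonlesional against healthy, the 7.1.0 libraries alone ended all 5 keratinocyte calls, both T/NK calls and ribosomal genes in fibroblasts, and the 7.2.0 libraries alone ended interferon gamma in endothelial cells. Sums of at least 50 cells ended ribosomal genes in keratinocytes and fibroblasts, the 10% mitochondrial limit and the version term ended them in keratinocytes, that limit or doublets kept ended keratinocyte markers in T/NK cells, and the marker-led clusters ended type I interferon. Lesional against nonlesional, the 7.1.0 libraries alone ended interferon gamma, class I, class II and heat shock genes in keratinocytes and both calls each in T/NK and myeloid cells. The 7.2.0 libraries alone ended interferon gamma, adhesion and cell cycle in keratinocytes, the regulatory T cell list and mitochondrial genes in fibroblasts. The 10% mitochondrial limit ended interferon gamma, class II and cell cycle in keratinocytes, and the marker-led clusters ended class II, cell cycle and heat shock genes. The version term ended cell cycle genes and myeloid class II, no filter ended keratinocyte interferon gamma and the regulatory T cell list, and doublets kept ended keratinocyte interferon gamma. Sums of at least 50 cells ended both T/NK calls and myeloid ribosomal genes, removal at the expected rate ended both myeloid calls, and sums of at least 10 cells ended myeloid class II. The cause was not tested.

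With the donor as a block, lesional against nonlesional, edgeR called 5 genes in keratinocytes, 4 in fibroblasts and 89 in myeloid cells, where only 2 pairs remain. The block turned RPL27 in myeloid, lesional versus nonlesional, to 0.0639, the ribosomal protein list in myeloid cells to 0.10 and the regulatory T cell genes list in T/NK, lesional versus nonlesional, to -0.0773. Sums of at least 50 cells put that list at -0.16, and the 7.1.0 libraries alone put heat shock genes in keratinocytes (lesional against nonlesional) at 0.11. The paired sign-flip test of shares could change no call, because no share was called before and its smallest p with 5 pairs is 0.0625. The counts of genes for T/NK and endothelial cells stayed at 0.

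With each library left out in turn, the counts of genes were 0 to 5 in keratinocytes, 0 to 2 in T/NK cells, 0 to 4 in fibroblasts and 0 to 1 in endothelial cells for lesional against healthy, 0 to 2 in T/NK cells for nonlesional against healthy and 0 to 4 in myeloid cells for lesional against nonlesional skin. List calls were 8 to 19 for nonlesional against healthy and 10 to 27 for lesional against nonlesional skin. The melanocyte share difference was -2.14 to -1.10 (lesional against healthy), -0.24 to 1.99 (nonlesional against healthy) and -3.77 to -1.54 (lesional against nonlesional). That of the T/NK share was 0.608 to 3.47, -0.311 to 2.22 and -0.265 to 2.81 in the same order. Lesional against healthy, S100A8 ranged from -3.34 to 0.31, IFNG from -0.85 to 0.97 and GZMB from -1.03 to 0.75. Nonlesional against healthy, S100A8 ranged from -2.28 to 1.65, IFNG from -2.20 to 1.38, RPS4X in fibroblasts from -0.0354 to 0.69, the ribosomal protein list from -0.11 to 0.46 in fibroblasts and from -0.28 to 0.0562 in keratinocytes. Lesional against nonlesional, IFNG ranged from -0.74 to 1.77 and COL1A1 in fibroblasts from -0.53 to 0.43.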

Other observations

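Genes and classes in this part were chosen after their values were seen. HES1 was also low in keratinocytes, at 178 ± 95.8 CPM in lesional (n = 6), 273 ± 63.4 in nonlesional (n = 4) and 473 ± 148 in healthy libraries (n = 4), a log2 fold change of -1.44 (SE 0.322) for lesional against healthy skin that did not pass (adjusted p = 0.182). With a 10% mitochondrial limit HES1 was the 1 gene called in that comparison. In nonlesional fibroblasts HES1 was at 91.7 ± 17.3 CPM (n = 4), a log2 fold change of -1.09 against healthy skin (adjusted p = 0.753), and in endothelial cells the lesional change was -0.43. DLK2 in nonlesional keratinocytes was at 14.6 ± 3.46 CPM (n = 4), between the healthy and the lesional level.

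In nonlesional T/NK cells, ZNF683, a transcription factor of tissue-resident T cells, was at 180 ± 54.0 CPM (n = 4) against 37.3 ± 21.8 in healthy ones (n = 5; log2 fold change 2.18, SE 0.451) and 124 ± 71.9 in lesional ones (n = 5). FXYD2 was at 167 ± 67.5 against 23.4 ± 25.7 CPM (3.18, SE 0.636). Both had an edgeR adjusted p of 0.0546 and were the 2 genes called in this comparison by DESeq2 and with RLE size factors. The fixed list of tissue-resident memory genes was called neither in nonlesional (median -0.30, adjusted p = 0.66) nor in lesional against healthy T/NK cells (median -0.06, adjusted p = 0.906).

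With sums of at least 10 cells, myeloid cells could be compared with healthy skin over 2206 genes. Healthy skin gave only 90 myeloid-like cells over 6 libraries, and both comparisons share these healthy sums. The calls below were not tested with libraries left out or in splits. In edgeR, HMGB2, a chromatin protein of dividing cells, rose in lesional (log2 fold change 2.53, SE 0.498, adjusted p = 0.045) and in nonlesional myeloid cells (2.94, adjusted p = 0.0289). BATF3, a factor of dendritic cells, fell in lesional ones (-2.45, adjusted p = 0.016), as did AUTS2 (-1.71, adjusted p = 0.045), and HIST1H4C rose in nonlesional ones (2.16, adjusted p = 0.0289). With sums of at least 5 cells, melanocytes of nonlesional and healthy skin differed in 0 of 889 genes by edgeR (37 at an unadjusted p under 0.05). There the log2 fold changes were 0.32 for PMEL, 0.30 for MLANA and 0.45 for TYR, with adjusted p from 0.936 to 0.974. CXCL9 in fibroblasts gave 453 UMIs in lesional skin (72.1 CPM of the pooled UMIs), of which 380 came from 1 library, 163 in nonlesional skin (54.1 CPM), all from 1 library, and 2 in healthy skin (1.36 CPM). FLG, the barrier protein filaggrin, gave 387 UMIs in lesional keratinocytes (29 CPM of the pooled UMIs), of which 355 came from 1 library, 73 in nonlesional (12.6 CPM) and 5 in healthy ones (1.09 CPM).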
